A study of Mus musculus with 14 samples.

How the data were processed

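Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open DNA and adds sequencing adapters to it. The cells were erythro-myeloid progenitors, the yolk sac cells that give rise to red cells and myeloid cells, sorted from mouse embryos at stage E10.5. Ezh2 is the catalytic subunit of Polycomb repressive complex PRC2, which methylates histone H3 at lysine 27. All embryos carried floxed Ezh2, and the knockout (KO) embryos also carried a Cre transgene driven by Tie2 (Tek) or by Vav1 regulatory sequence, per the labels. The wild type (WT) embryos lacked the transgene, per the labels. The 14 samples form 4 groups of 3 Tie2 WT, 5 Tie2 KO, 3 Vav KO and 3 Vav WT.

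The submitters' processing notes name the mm10 build and FastQC, Bowtie2, SAMtools 1.3.1, Picard, MACS2 2.1.2 and HOMER 4.10, with no role for each. Whether reads were shifted for the Tn5 cut, how duplicates were treated, how libraries were scaled and which test called the regions are not given in the sources used here. The 6 files used here are lists of regions that the authors called as differing between groups of samples, with 1 list of higher and 1 of lower regions for each of 3 comparisons. The group abbreviations in the names of these lists were read as Tie2 KO, Tie2 WT and Vav KO. No list names Vav WT, so those 3 samples enter no comparison, and Vav KO was compared with Tie2 WT, a control from the other Cre line.

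Each line pairs a region with a gene. Per the file headers, the deposited values are a log2 fold change and an adjusted p-value for each region, made by the authors. Per the file headers, the deposited lists also give other measures, the width of the region and its distance to the gene start in bp. Tested on the files, the smallest absolute log2 fold change was 0.58 and the largest adjusted p-value was 0.0479. Every region either covered a gene start or ended within 5 kb of one, the largest distance being 4999 bp. Region edges lay on a grid of 100 bp and the smallest width was 999 bp. The region numbers in the lists run higher than the number of regions, up to 9976 in the list of 2959 regions higher in Tie2 KO than in Tie2 WT, so each list is part of a longer one. What happened to the other regions, and which regions were tested, is not given in the sources used here.

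The lists hold no value per sample. Depth per sample is therefore unknown, replicate spread cannot be computed, and the authors' adjusted p-value is the error given for a single region. The tests below compare lists of regions or genes. Neighbouring regions are not independent replicates, so their p-values and the exact 95% binomial intervals describe the lists and not the spread between embryos.

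The 10679 lines hold 9954 distinct regions over the 3 comparisons, counted separately in each, of which 694 were paired with more than 1 gene. Gene identifiers were matched to a table of RefSeq genes of assembly GRCm38.p6, which was used for names and gene types only. Of the lines, 10669 matched, and 9 lines in which a symbol had turned into a calendar date got their symbol back through the identifier. Coordinates are those of the deposited lists, in mm10.

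The split of regions by direction was set against an even split with an exact two-sided binomial test. The planned classes of promoter, exon, intron and intergenic regions are not in the lists, so a region was classed as covering a gene start or lying upstream of one. The share covering a gene start was compared between higher and lower regions with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 3 comparisons. Distances to the gene start were compared by a permutation test of the difference in median log10(distance + 1) with 100000 resamples, for which the smallest possible p is 1e-05. Regions of 2 comparisons were matched by an overlap of at least 1 bp. For agreement in direction between comparisons that share a group, unchanged groups of the same sizes were simulated 2000000 times. The 12 gene lists were tested with Fisher's exact test, two-sided, on genes near higher regions only against genes near lower regions only, with Benjamini-Hochberg adjustment over all 36 tests. Odds ratios had 0.5 added to each cell.

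The named genes follow a rule set before the data were examined. It takes Ezh2, Tek and Vav1, and for each comparison and direction the 8 regions with the largest fold change and the 5 genes with the most regions. It also takes up to 4 members with the largest fold change from each gene list past an adjusted p of 0.05. Some genes that the rule or the lists take are not reported here. Other genes are named as examples of list members or of low counts, and were chosen after their values were seen. The gene lists cover erythroid, myeloid, megakaryocyte and mast, haematopoietic progenitor, endothelial, lymphoid, Wnt signalling, developmental transcription factor, Polycomb machinery, cell cycle inhibitor, fetal programme and other yolk sac cell genes. They were also set before the data were examined. Sets of neural, Y-linked and X-linked escape genes were written after the results had been seen. The housekeeping genes, taken by symbol as ribosomal protein, proteasome, RNA polymerase II and translation initiation factor genes, were chosen after the lists of regions had been looked at but before their own counts had been seen.

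Alternatives were only regions at or above the comparison's median absolute fold change, merging of regions within 10 kb, leaving out X and Y, 1 region per gene, a reciprocal overlap of 50%, the same gene in place of the same region, another background for the gene lists, and regions counted in place of genes. Added after seeing the data were regions of the smallest width only, a region midpoint within 500 bp of the gene start, 1 gene per 1 Mb bin, regions within 1 kb of the gene start, and leaving out X and Y for the gene lists and for the difference between the knockouts. The smallest width was applied to gene starts and to the difference between the knockouts. The planned comparison of sequence motifs was not run, since no genome was used here.

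The list test was tested on simulated data. With directions shuffled over the 3467 genes of Tie2 KO against Tie2 WT, 2 of 600 random lists of 40 genes were called after adjustment. A planted list of 100 genes with an odds ratio of 4 was recovered in 100% of 50 draws, judged on its unadjusted p. All genes of these simulated lists lay near a called region. Only the developmental list, with 195, had more than 100 such genes in that comparison. Wnt genes came next, with 45 near higher and 1 near lower regions. The recovery therefore does not show how often the test would find the shorter lists. The overlap counts were checked against bedtools 2.31.1. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.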

Results

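The data describe open chromatin in erythro-myeloid progenitors of the mouse yolk sac at stage E10.5, in which Ezh2 was deleted with Tie2-Cre, active in endothelium and the blood cells that arise from it, or with Vav-Cre, active in blood cells. Lists of regions called by the authors cover 3 groups of 3 Tie2 WT, 5 Tie2 KO and 3 Vav KO samples. They hold only regions at a gene start or within 5 kb upstream of one, so distant enhancers are not covered, and the depth of each sample is unknown. Fold changes and adjusted p-values of single regions are the authors' own, with no replicate values behind them here, and coordinates are in mm10.

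The comparison of Tie2 KO with Tie2 WT asks how chromatin near genes differs when Ezh2 is deleted early, with the endothelial driver. Accessibility was mostly higher: 2959 regions near 2833 genes were higher and 619 regions near 656 genes were lower. Genes of developmental transcription factors stood out, with 195 of 260 near a higher region and 0 near a lower one. Wnt pathway genes also lay near higher regions, 45 of 104, against 1 near a lower region. Megakaryocyte and mast cell genes went the other way, with 7 of 32 near a lower region and 1 near a higher one. The median log2 fold change was 1.02 for higher and -0.86 for lower regions, and 82.7% of regions were higher (exact 95% interval 81.4% to 83.9%).

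The developmental list differed between genes near higher and lower regions with an adjusted p of 2.46e-17 by Fisher's exact test and an odds ratio of 96.1. Near higher regions lay 32 of 39 Hox genes, the clustered genes that set position along the body axis, with log2 fold changes from 0.78 to 2.08. So did 7 of 8 Tbx genes, 9 of 11 Nkx genes and 6 of 6 Dlx genes, while 11.5% of all protein-coding genes in the reference table lay near a higher region. Among the largest fold changes of the list in the authors' deposited table were those of Tbx3, a T-box regulator of limb and heart development, at a log2 fold change of 2.34, Gsx2 at 2.25 and Hoxa11 at 2.08. The Tbx3 region lay on chromosome 5 from 119663702 to 119666400, 4461 bp upstream of the gene start, with an adjusted p of 4.26e-06 in the authors' deposited table. Hoxa7 and Pax3, a regulator of neural crest and muscle precursors, had 4 higher regions each, as did the noncoding RNA gene Plut.

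Among Wnt genes, 15 of 19 ligand genes, 8 of 10 genes of secreted inhibitors, 3 of 10 Frizzled receptor genes and 1 of 4 TCF/LEF genes lay near a higher region. The adjusted p of the Wnt list was 0.0123 by Fisher's exact test, with an odds ratio of 7.04. In the authors' deposited table the largest log2 fold changes were 1.64 at Lef1, a transcription factor of the pathway, 1.61 at Sfrp1, 1.5 at Dkk2 and 1.41 at Cxxc4. Sfrp1 and Dkk2 encode secreted inhibitors of the pathway. The only Wnt gene near a lower region was Ctnnbip1, an inhibitor that binds beta-catenin, with a log2 fold change of -1.08 in the authors' deposited table. Among regions at or above the median fold change the call of the Wnt list was lost (adjusted p = 0.834 by Fisher's exact test), and over all alternatives its adjusted p ranged from 5.69e-06 to 0.834.

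Lower regions of the megakaryocyte and mast list lay near Treml1, Clec1b and Gp6, receptors of platelets, and Cpa3, a protease of mast cells. Their log2 fold changes in the authors' deposited table were -1.61, -1.47, -1.33 and -1.07. Other lower members included Tubb1 and F2rl2, and the single higher member was Rab27b. The adjusted p of the list was 0.000605 by Fisher's exact test, with an odds ratio of 0.0453. Over the alternatives it ranged from 0.000276 to 0.0581, the call being lost where higher genes were set against all genes near any region. Of 178 housekeeping genes of ribosome, proteasome, RNA polymerase II and translation initiation, 7 lay near a higher and 15 near a lower region.

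The other 9 lists did not pass an adjusted p of 0.05 by Fisher's exact test of genes near higher against genes near lower regions. Of markers of other yolk sac cells, 22 of 52 (42.3%, against 11.5% of all protein-coding genes) lay near a higher region and 0 near a lower one (adjusted p = 0.0831 by Fisher's exact test). Of the 22, 11 are also on the developmental list. Endothelial genes numbered 19 near higher and 3 near lower regions, of 51 (adjusted p = 1 by Fisher's exact test), and Tek is among the 19. These are 37.3% and 5.88%, against 11.5% and 2.51% of all protein-coding genes. With higher genes set against all genes near any region, the log2 odds ratio of endothelial genes was 1.34 (adjusted p = 0.0553 by Fisher's exact test). On that background other yolk sac markers passed the threshold, at 2.04 (adjusted p = 0.00319 by Fisher's exact test). Myeloid genes passed it as rarer among higher genes, at -4.20 (adjusted p = 0.00981 by Fisher's exact test). The 3 lower endothelial genes were Pecam1, Lyve1 and Icam2, at -0.77, -0.67 and -0.65 in the authors' deposited table. Lymphoid genes numbered 10 higher and 1 lower, erythroid genes 5 and 2, haematopoietic progenitor genes 5 and 1, and the myeloid list had 1 lower gene, Tyrobp. Cell cycle inhibitor genes numbered 5 higher and 1 lower, among them Cdkn2a at a log2 fold change of 0.98 and Cdkn2b at 0.71 in the authors' deposited table. Polycomb genes numbered 5 higher and 1 lower, with Cbx2 at 1.86 in the authors' deposited table, and fetal programme genes 3 higher and 2 lower. The adjusted p of these lists lay between 0.419 and 1 by Fisher's exact test of genes near higher against genes near lower regions.

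Of single regions, the largest rises in the authors' deposited table were at Lad1, with a log2 fold change of 3.0, Tek at 2.90, Sulf1, an enzyme that edits heparan sulfate, at 2.86, Mir9-3 at 2.77 and Mir125b-1 at 2.73. Ppp1cc, Ndufa9 and Ptk6 followed at 2.63, 2.54 and 2.53 in the authors' deposited table. The largest falls in the authors' deposited table were at Eef1g, at -2.56, Atp5l at -2.45, Kansl2 at -2.26 and Snord91a at -1.97. Each of these regions had an adjusted p of 0.00132 or lower in the authors' deposited table. Ftx, a noncoding RNA gene of the X inactivation centre, had 2 lower regions, at -1.32 and -0.84 in the authors' deposited table.

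Higher regions covered a gene start more often than lower ones, 1644 of 2959 (55.6%) against 114 of 619 (18.4%), with an adjusted p of 2.66e-67 by Fisher's exact test. The median distance to the gene start was 0 bp for higher and 1455 bp for lower regions (permutation test, two-sided, p = 1e-05, the smallest the permutations can give). Higher regions were wider, with a median of 1599 bp against 1099 bp, and a wide region covers a gene start more easily. Among regions of the smallest width, a choice made after seeing the data, the shares were 21.7% and 14.1% (adjusted p = 0.00878 by Fisher's exact test).

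**Figure D1:**
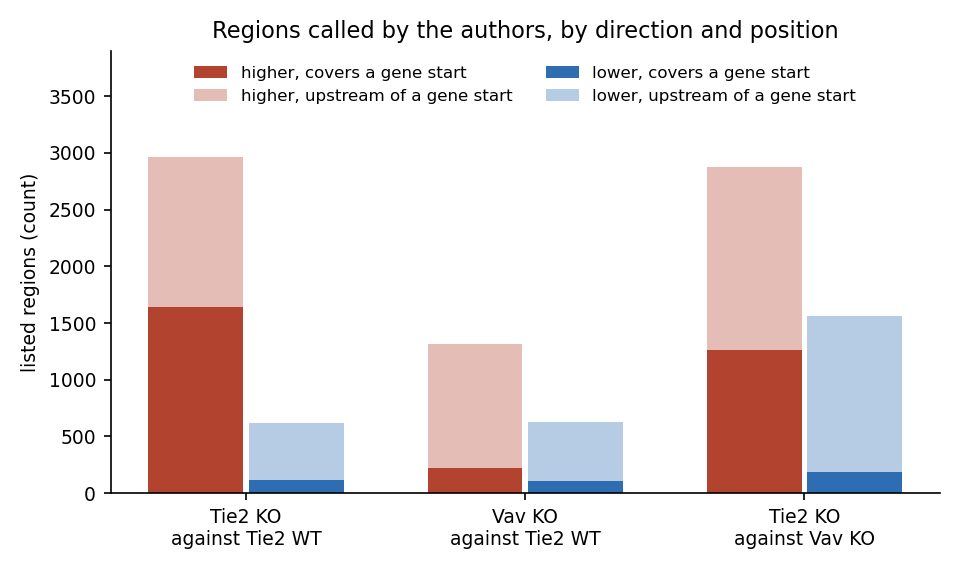
Bars count the regions the authors called for each comparison on the vertical axis, red for higher and blue for lower, with the dark part covering a gene start and the pale part upstream of one. Higher regions covered a gene start in 55.6% of cases for Tie2 KO against Tie2 WT and in 16.8% for Vav KO against Tie2 WT.

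The comparison of Vav KO with Tie2 WT asks the same of the blood driver, though with a control from the other Cre line, so line and genotype cannot be told apart in it. In total, 1313 regions near 1347 genes were higher and 630 regions near 657 genes were lower, 67.6% being higher (exact 95% interval 65.4% to 69.7%). Of 260 developmental transcription factor genes, 25 lay near a higher region (9.62%, exact 95% interval 6.32% to 13.9%, against 5.29% of all protein-coding genes). Near a lower one lay 10 (3.85%, exact 95% interval 1.86% to 6.96%, against 2.59%). Without Hoxd10, which lay near both, the split of 24 and 9 gave an adjusted p of 1 by Fisher's exact test against other genes. Set against all genes near any region, which include those called in Tie2 KO, the list was rarer among both higher genes (log2 odds ratio -1.01, adjusted p = 0.00319 by Fisher's exact test) and lower genes (1.19, with the sign turned so that above 0 means rarer among lower genes, adjusted p = 0.0244 by Fisher's exact test). Hox genes numbered 4 on each side, with Hoxd10 on both. The same Tie2 WT samples serve this and the previous comparison, so agreement between them is no independent repeat. Megakaryocyte and mast genes lay near lower regions here too, 4 of 32 with 0 near higher ones (adjusted p = 0.0477 by Fisher's exact test).

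Those 4 genes were Treml1, Rab27b, Hdc, the enzyme that makes histamine, and Gp1bb, with log2 fold changes of -2.1, -1.65, -1.29 and -0.87 in the authors' deposited table. The call of this list was lost among regions at or above the median fold change (adjusted p = 0.39 by Fisher's exact test), and over all alternatives its adjusted p ranged from 0.0395 to 0.39. Of haematopoietic progenitor genes, Gata2, Cd93, Meis1 and Cd48 lay near lower regions and Prdm16 near a higher one (adjusted p = 0.118 by Fisher's exact test), with Gata2, a regulator of blood stem cells, at -1.55 in the authors' deposited table. Erythroid genes numbered 7 near higher and 0 near lower regions (adjusted p = 0.267 by Fisher's exact test), among them the erythropoietin receptor gene Epor at 1.7 in the authors' deposited table. Wnt genes numbered 14 higher and 3 lower (adjusted p = 0.562 by Fisher's exact test). The counts of higher and lower genes were 7 and 2 for other yolk sac cells, 4 and 1 for endothelial and 3 and 4 for Polycomb genes. They were 1 and 1 for myeloid and fetal programme genes, 1 and 0 for cell cycle inhibitors and 0 and 0 for lymphoid genes. The adjusted p of these lists lay between 0.468 and 1 by Fisher's exact test.

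The largest fold changes of this comparison lay at genes outside the lists. In the authors' deposited table, log2 fold changes reached 5.30 upstream of Sumf1, 5.06 upstream of Prss41, 4.63 upstream of Mir7661, 4.02 upstream of both Stmn3 and Rtel1, and 3.94 upstream of Klf14. The largest falls in the authors' deposited table were -3.74 upstream of 6430584L05Rik, -3.73 upstream of Nbeal1, -3.53 upstream of Slc34a1 and -3.50 upstream of Rfx4, and a region over the gene start of Rfx4 was higher, at 0.83. Gm11762 had 3 regions, of which 2 were lower and 1 was higher. Higher and lower regions covered a gene start about as often, 16.8% and 16.3% (adjusted p = 0.845 by Fisher's exact test). The median distance was 1522 bp for higher and 1078.5 bp for lower regions (permutation test, two-sided, p = 0.00174).

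The direct comparison of Tie2 KO with Vav KO asks where the knockouts differ. Here 2873 regions near 2755 genes were higher in Tie2 KO and 1560 regions near 1610 genes were lower, with 64.8% higher (exact 95% interval 63.4% to 66.2%). The Tie2 KO samples are those also compared with Tie2 WT. Developmental transcription factors lay near higher regions here too, 194 of 260, and 3 lay near a lower region (Tbx1, Foxc2 and Foxe3). Without Tbx1 and Foxe3, which lay near both, the split of 192 and 1 had an adjusted p of 9.73e-36 by Fisher's exact test and an odds ratio of 78.7. By Fisher's exact test, Wnt genes numbered 34 higher and 5 lower (adjusted p = 0.0127), other yolk sac markers 20 and 0 with 1 more near both (adjusted p = 0.00178), and Polycomb genes 11 and 0 (adjusted p = 0.0477).

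Within the developmental list the largest log2 fold changes in the authors' deposited table were 4.72 at Irx2, 3.09 at Hoxc6, 3.01 at Six6 and 2.75 at Lbx2. Among Wnt genes the authors' deposited table gives 2.2 at Lef1, 2.1 at the receptor gene Ror1, 2.06 at Bambi and 1.92 at Dkk1. Other yolk sac markers in the authors' deposited table were led by Krt19, an epithelial keratin, at 3.82, Twist2 at 2.93, Foxa1 at 2.31 and Hand1 at 2.3, and 10 of the 21 higher ones are also on the developmental list. Polycomb members in the authors' deposited table were led by Aebp2 at 1.94, a partner of PRC2, Kdm2b at 1.79, Cbx2 at 1.56 and Pcgf1 at 1.11. Among regions at or above the median fold change the calls of the Polycomb, Wnt and other yolk sac lists were lost by Fisher's exact test. Over the alternatives their adjusted p by Fisher's exact test ranged from 0.0395 to 1, from 0.00693 to 0.265 and from 0.000254 to 0.174.

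The remaining lists did not pass the threshold by Fisher's exact test. By that exact test, counts of higher and lower genes were 16 and 2 for endothelial (adjusted p = 0.0868), 3 and 8 for megakaryocyte and mast (adjusted p = 0.0831), 3 and 6 for erythroid (adjusted p = 0.223) and 4 and 7 for haematopoietic progenitor genes (adjusted p = 0.267). They were 7 and 5 for myeloid, 9 and 2 for lymphoid, 5 and 2 for fetal programme and 3 and 1 for cell cycle inhibitor genes, with 1 more of the last near both, with adjusted p between 0.625 and 1 by Fisher's exact test. Of 178 housekeeping genes, 6 lay near a higher and 32 near a lower region. Outside the lists, the largest log2 fold changes in the authors' deposited table were 5.17 upstream of Dok3 and 4.54 at Dlg2, a synaptic scaffold, and on the lower side -4.55 upstream of Chst2 and -4.39 upstream of Fam185a. Gad1os had 4 higher regions and Sdf4 had 3 lower ones. Higher regions covered a gene start in 43.8% of cases and lower ones in 12% (adjusted p = 3.41e-113 by Fisher's exact test), and among regions of the smallest width in 19.5% and 9.49%.

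**Figure D2:**
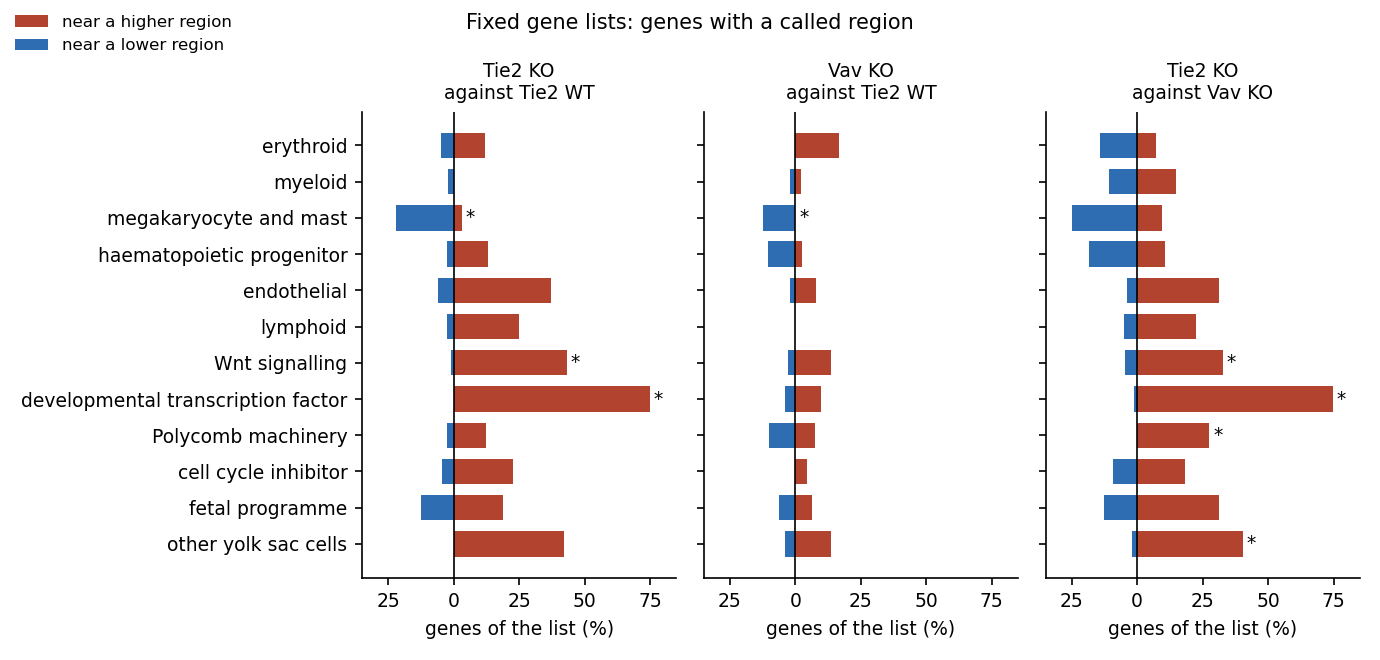
Horizontal bars give the percent of each fixed list's genes near a higher (red, to the right) or a lower (blue, to the left) region in each comparison, and an asterisk marks an adjusted p under 0.05 by Fisher's exact test. The developmental transcription factor bar reaches 75% in Tie2 KO against Tie2 WT and 9.62% in Vav KO against Tie2 WT.

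The effects of the knockouts against Tie2 WT were compared directly. The share of higher regions was 82.7% in Tie2 KO and 67.6% in Vav KO (Fisher's exact test, two-sided, p = 1.59e-36), and the share of higher regions over a gene start was 55.6% and 16.8% (p = 8.64e-132). Both differences shrank among regions of the smallest width, a choice made after seeing the data, where 67.1% and 63.8% were higher (Fisher's exact test, two-sided, p = 0.152). Gene starts were covered there by 21.7% and 14% of higher regions (Fisher's exact test, two-sided, p = 0.000648). That width kept 21% of the higher regions of Tie2 KO and 42.9% of those of Vav KO, so it also selects on direction. With regions within 10 kb merged the differences were 13.9 and 46.2 points. Developmental transcription factors made up 6.88% of genes near higher regions in Tie2 KO and 1.86% in Vav KO (adjusted p = 2.62e-12 over 12 lists by Fisher's exact test). No other list passed this test, the next smallest adjusted p being 0.218 for lymphoid genes.

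Regions of both comparisons overlapped in 452 pairs. In 314 pairs both were higher, in 84 both were lower, and in 54 the directions were opposite, so that 88.1% agreed in direction. In simulation, unchanged groups that share the Tie2 WT samples agreed in 99.98% of pairs called in both at the 5% level and in 99.9% at the 10% level, which lie above the observed share. The simulation takes the same region in both comparisons, while observed pairs may share as little as 1 bp, so the shares are not strictly alike. Of the 21900 protein-coding genes in the reference table, which stand in for the genes tested, 379 lay near higher regions in both comparisons, where independent lists would share 133.8, and 85 lay near lower regions in both, where 14.3 would be shared. Genes in opposite directions numbered 83 near regions higher in Tie2 KO and lower in Vav KO, where 65.6 would be shared, and 30 the other way, where 29.1 would be. Part of this excess may come from the shared Tie2 WT samples, which cannot be split with no values per sample. Of the 54 opposite pairs, 42 were higher in Tie2 KO and lower in Vav KO. With a reciprocal overlap of 50%, 284 pairs were left, of which 95.4% agreed and 13 were opposite. Of the 13, 10 were higher in Tie2 KO, among them Lpar3, Ptgfr and Rab27b. Their log2 fold changes in the authors' deposited table were 0.84, 0.77 and 0.79 in Tie2 KO and -1.24, -1.36 and -1.65 in Vav KO.

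**Figure D3:**
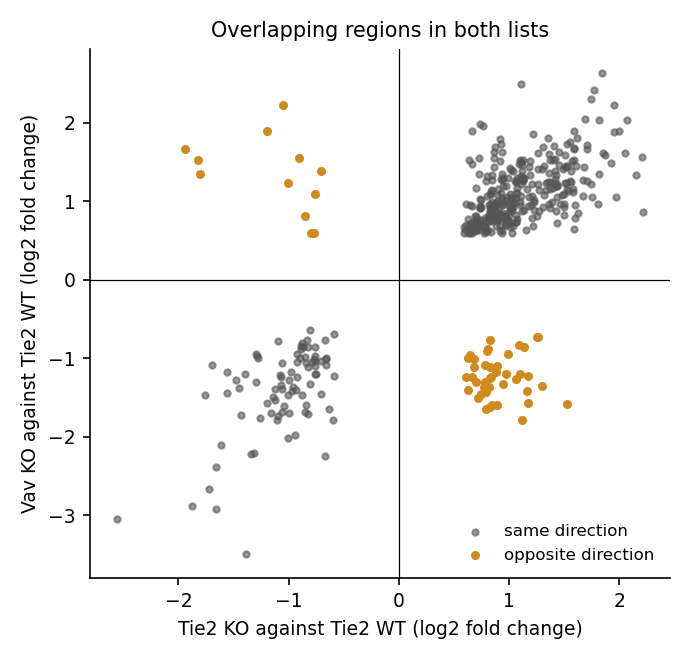
Each point is a pair of overlapping regions, with the authors' log2 fold change of Tie2 KO against Tie2 WT on the horizontal axis and that of Vav KO against Tie2 WT on the vertical axis. Of the 452 pairs, 398 share their direction (grey) and 54 do not (orange).

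The other comparisons also share groups. Tie2 KO against Tie2 WT and Tie2 KO against Vav KO had 1751 overlapping pairs, of which 99.2% agreed in direction. Simulated unchanged groups gave 99.9%, 98.8% and 97.2% with regions called at the 1%, 5% and 10% level. The observed share lies below the first and above the others. The authors' limits on adjusted p and fold change match none of these levels, so this cannot decide between change and no change. Vav KO against Tie2 WT and Tie2 KO against Vav KO had 639 pairs, and with Vav KO placed on the same side 84% agreed, where simulated unchanged groups gave 99.8% or more at each of these levels. The simulation takes the same region in both comparisons, while these pairs may share as little as 1 bp. With a reciprocal overlap of 50%, 97.3% of 476 pairs agreed.

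No region near Ezh2 itself was in any of the 6 lists. The lists show changes in accessibility and do not show whether the floxed part was deleted. At Tek, the gene whose promoter drives Tie2-Cre, a region on chromosome 4 from 94736902 to 94749800 was higher in Tie2 KO than in Tie2 WT, with a log2 fold change of 2.90 and an adjusted p of 0.00132 in the authors' deposited table. It spans 12899 bp, from 2387 bp upstream to 10511 bp downstream of the gene start, and was the widest region of its list, the next being 7999 bp. Against Vav KO the authors' deposited table gives Tek a log2 fold change of 2.92. At Vav1, on chromosome 17 from 57277502 to 57280000, the authors' deposited table gives 0.81 in Vav KO against Tie2 WT and -0.90 in Tie2 KO against Vav KO. No Vav1 region was listed in Tie2 KO against Tie2 WT, and no Tek region in Vav KO against Tie2 WT.

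**Figure D4:**
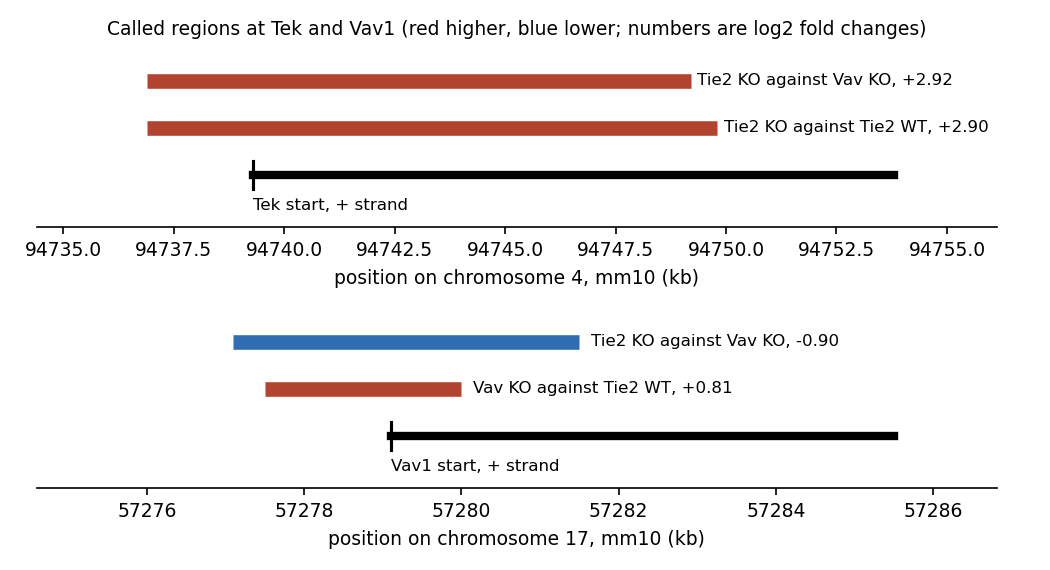
Bars mark the called regions at Tek and Vav1 along the chromosome in kb (mm10), red for higher and blue for lower, with the log2 fold change beside each and the first part of the gene in black. The Tek region of Tie2 KO against Tie2 WT spans 12899 bp, and the Vav1 regions span 2499 bp and 4399 bp.

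On the X chromosome lay 1.82% of higher and 3.39% of lower regions in Tie2 KO against Tie2 WT (adjusted p = 0.0587 by Fisher's exact test), 1.29% and 2.7% in Vav KO against Tie2 WT (adjusted p = 0.0602), and 1.46% and 2.18% in Tie2 KO against Vav KO (adjusted p = 0.0896). Uty, on the Y chromosome, had a log2 fold change of 0.99 in Tie2 KO and 1.29 in Vav KO against Tie2 WT, and of -1.94 in Tie2 KO against Vav KO, in the authors' deposited table. The last value is larger in size than the gap between the others, so they may not describe the same stretch of Uty. Eif2s3y, also on the Y chromosome, was at 1.82 in Vav KO against Tie2 WT in the authors' deposited table. The sex of the embryos is not in the labels.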

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

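The differences between the knockouts were part of the plan. The tests of explanations below were chosen after the results they bear on had been seen, except the test of housekeeping genes near higher regions.

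Effects against Tie2 WT differed between Tie2 KO and Vav KO in 3 ways. The share of higher regions was 15.12 points larger in Tie2 KO, the share of higher regions over a gene start was 38.73 points larger, and developmental transcription factors made up 5.03 points more of the genes near higher regions, each by Fisher's exact test on regions or genes. Among regions of the smallest width, a choice made after seeing the data, the first was 3.23 points (Fisher's exact test, two-sided, p = 0.152) and the second 7.71 points. That width kept 21% of higher and 49.3% of lower regions in Tie2 KO, against 42.9% and 50.6% in Vav KO. It thus drops higher regions of Tie2 KO most and cannot decide whether width explains the differences. At or above the median fold change they were 18.2 and 43.8 points, and with regions within 10 kb merged 13.9 and 46.2 points. Vav KO has no control from its own line here, and the groups hold 5 and 3 samples, so the Cre line and the number of samples differ along with the effect.

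Developmental transcription factor genes near higher regions in Tie2 KO are the first pattern. A library bias toward GC-rich gene starts, acting alone, is argued against by housekeeping genes, of which 7 of 178 lay near a higher region with an upper bound of 7.93%. Lower signal at these genes, which stays open below, could hide such a bias. These genes cannot tell the 2 together from neither, and the GC content of regions was not compared. Other yolk sac cells in the sort stay open. Of their markers outside the developmental list, 11 of 40 lay near a higher region (27.5%, lower bound 14.6%, against 11.5% of all protein-coding genes), which goes with them. Such a share is not particular to these markers and cannot decide, since Wnt genes reached 43.3% and endothelial genes 37.3%. Lymphoid genes were at 25% and myeloid genes at 0%. Of 76 neural genes 63 lay near a higher region (lower bound 72.53%), but this cannot decide either. All 76 are on the developmental list, itself at 75%, and the set was written after that was seen. Whether yolk sac cells keep neural genes closed was not measured here. Endothelial cells in the sort were not tested as a source, though 19 of 51 endothelial genes lay near a higher and 3 near a lower region. Lower signal over background in the Tie2 KO libraries also stays open: 15 of the 178 housekeeping genes lay near a lower region, a lower bound of 4.79% against 2.51% of all protein-coding genes, which goes with it, while lower regions covered gene starts less often than higher ones, which goes against it. Loss of Ezh2 stays open too: the 75% of the list near a higher region is the pattern itself and tests no cause, Vav KO, also labelled as an Ezh2 knockout, had 25 of 260 (9.62%, against 5.29% of all protein-coding genes), and the Cre transgene goes with the genotype.

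The wide Tek region in Tie2 KO and the Vav1 region in Vav KO are the second pattern. Loss of Ezh2 in both knockouts was predicted to leave Vav1 higher in Tie2 KO than in Vav KO. It was lower, with a log2 fold change of -0.90 in the authors' deposited table. That value shares the Vav KO samples with the 0.81 that makes the pattern, and its direction had been seen first. It therefore does not decide. The fall in Tie2 KO against Vav KO is about as large as the rise in Vav KO against Tie2 WT. No Vav1 region was listed in Tie2 KO against Tie2 WT either, so the lists show no opening of Vav1 in Tie2 KO. With no values per sample, an opening too small to be called cannot be excluded. Extra copies of regulatory sequence on the Cre transgenes stay open: the Tek region was wider than about 99.97% of higher regions in both Tie2 KO comparisons and Vav1 was higher in Vav KO, but these values are the pattern itself and test no cause. For Tek, the log2 fold change of Tie2 KO in the authors' deposited table was 2.90 against Tie2 WT and 2.92 against Vav KO. With these near-equal values and no Tek region in Vav KO against Tie2 WT, the lists show no rise of Tek in Vav KO. This argues against a rise of Tek common to both Ezh2 knockouts. Within Tie2 KO, loss of Ezh2 cannot be told apart from the transgene, since those samples have both.

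Genes of the sex chromosomes are the third pattern. Whether a larger share of male embryos in Tie2 KO than in Tie2 WT underlies the higher Uty region stays open, since sex is not in the labels. The share of regions on X did not differ between higher and lower regions past the threshold (adjusted p = 0.0587 by Fisher's exact test). That share cannot decide, since X-linked genes under X inactivation need not differ between the sexes. Of 7 regions of genes that escape X inactivation, a set written after the results had been seen, 5 were lower (Ftx with 2 regions, Kdm5c, Kdm6a and Jpx), and those at Shroom4 and Bgn were higher. Of all regions of this comparison 17.3% were lower. The lower escape genes go with more males, but a set written after the results cannot decide. In Tie2 KO against Vav KO, Uty was lower and so were 2 escape gene regions, at Ftx and Kdm5c, with Shroom4 higher. Sex therefore cannot be told apart from an effect of genotype in either comparison.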

How the results depend on the processing

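The alternatives of smallest width, midpoint, 1 Mb bin, 1 kb distance, gene lists without X and Y, and the knockout difference without X and Y or at the smallest width were chosen after seeing the data. Of 295 alternative values with a direction, 240 kept their direction and their side of the threshold, among them every split by direction, distance and overlap result and the developmental transcription factor calls in both Tie2 KO comparisons. Of 21 alternative counts of lists called, 15 stayed within 1.5 times the count they replace. The cause of the changes below was not tested. The difference in gene starts in Vav KO against Tie2 WT, 0.482 points, became -2.80 among regions at or above the median fold change, -1.33 at the smallest width and -0.15 by midpoint, none past the threshold. The difference in the share of higher regions between the knockouts fell from 15.12 to 3.23 points at the smallest width, not past the threshold.
The other values are log2 odds ratios of gene lists unless they count lists. For Tie2 KO against Tie2 WT, the Wnt call was lost above the median fold change (1.09), within 1 kb (1.79) and with lower genes set against all genes near any region (2.12), and the megakaryocyte and mast call with higher genes set against them (-2.50). For Vav KO against Tie2 WT, the megakaryocyte and mast call was lost above the median (-3.59), per 1 Mb bin (-3.97), within 1 kb (-3.66) and with higher (-2.66) or lower (-2.29) genes against all genes, and the number of lists called fell from 1 to 0 in the first 3 of these. For Tie2 KO against Vav KO, the number of lists called fell from 4 to 1 above the median, and to 2 within 1 kb and with higher genes against all genes. Calls lost there were Wnt above the median (1.82), within 1 kb (2.46) and with higher genes (0.90), Polycomb above the median (1.89), per 1 Mb bin (3.46), within 1 kb (1.61) and with higher (1.58) or lower (3.39) genes, and other yolk sac cells above the median (2.46) and within 1 kb (3.29).
Lists not called changed sign as follows. Above the median, developmental transcription factors (-1.03) and other yolk sac cells (-0.41) did so in Vav KO against Tie2 WT and cell cycle inhibitors (-0.18) in Tie2 KO against Vav KO. Per 1 Mb bin, progenitor (0.32) and cell cycle inhibitor (0.025) lists did so in Tie2 KO against Tie2 WT. Within 1 kb, endothelial genes (-0.98) did so in Tie2 KO against Tie2 WT, developmental transcription factors (-0.22) and cell cycle inhibitors (-0.84) in Vav KO against Tie2 WT, and myeloid (0.020) and fetal programme (-0.63) genes in Tie2 KO against Vav KO. With higher genes against all genes, cell cycle inhibitors (0.73) did so in Tie2 KO against Tie2 WT, endothelial (-0.52), developmental (-1.01), Polycomb (0.039) and cell cycle inhibitor (-0.52) genes in Vav KO against Tie2 WT, and myeloid genes (0.96) in Tie2 KO against Vav KO. Of the 27 sign changes the developmental one was past the threshold (adjusted p = 0.00319 by Fisher's exact test), and that background holds the developmental genes called in Tie2 KO. With lower genes against all genes, progenitor (0.075), endothelial (-0.28), lymphoid (-0.029) and Polycomb (0.17) genes did so in Tie2 KO against Tie2 WT and cell cycle inhibitors (-0.071) in Tie2 KO against Vav KO. With regions counted, progenitor genes (0.067) did so in Tie2 KO against Tie2 WT and cell cycle inhibitors (-0.033) in Tie2 KO against Vav KO, and without X and Y the Polycomb list (1.32) in Tie2 KO against Tie2 WT.
Results that were not past the threshold passed it in 8 cases, 3 of other yolk sac cells in Tie2 KO against Tie2 WT and 3 of megakaryocyte and mast genes in Tie2 KO against Vav KO. The others were myeloid genes in Tie2 KO against Tie2 WT with higher genes against all genes (-4.20) and developmental transcription factors in Vav KO against Tie2 WT with lower genes against all genes (1.19).
No paired analysis was possible because the groups compared share 0 replicate numbers and the lists hold no values per sample. For the same reason no replicate could be left out and no other split of the samples counted. Promoters within 5 kb and genes within 50 kb would take in every region, so neither alternative was run, nor were those on sequence.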

Other observations

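The genes named here and the counts of housekeeping genes outside Tie2 KO against Tie2 WT were chosen after seeing the data. Some erythroid genes lay near higher regions in both knockouts against Tie2 WT, though the erythroid list passed the test in neither comparison. Both comparisons use the same Tie2 WT samples, so genes that move alike in them are no independent repeat. Slc4a1, the band 3 anion exchanger of red cells, was at a log2 fold change of 0.87 in Tie2 KO and 0.97 in Vav KO in the authors' deposited table, and Epb42 at 0.71 and 0.75. Trim58 was at 1.97 in Tie2 KO and at 1.33 and 1.51 in Vav KO in the authors' deposited table, but these regions do not overlap, and another Trim58 region was lower in Tie2 KO than in Vav KO. Cd48 was at -0.89 in Tie2 KO and -0.84 in Vav KO in the authors' deposited table.

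Of 178 housekeeping genes, 32 lay near a lower region in Tie2 KO against Vav KO (18%, exact 95% interval 12.6% to 24.4%, against 6.35% of all protein-coding genes). In Vav KO against Tie2 WT, 4 lay near a lower and 10 near a higher region. Of the X-linked escape genes, 5530601H04Rik and Kdm5c lay near lower regions in Vav KO against Tie2 WT, and of the 76 neural genes 6 lay near a higher and 1 near a lower region there.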
